A study of Drosophila melanogaster with 12 samples.

How the data were processed

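The study hybridised total RNA of whole Drosophila melanogaster to Affymetrix DrosGenome1 arrays, per the labels from pools of 5 males and 5 females. Flies were either wild type or carried the S284Y mutation of the splicing factor subunit dU2AF50, whose gene is named U2af50 below, and were kept at 25C (permissive) or 30C (restrictive). There are 12 arrays in 4 groups of 3. Groups were taken from the sample titles. The descriptions of all 3 WT 30C arrays read 25C, and that of array 1 also carries the permissive wording, so moving array 1 to the WT 25C group was tried as an alternative. Nothing in the labels says that replicates came from separate cultures or pools of animals. P-values of single probe sets therefore measure only the spread between these samples. Those of gene lists compare the genes of a list with all other genes. The exact tests and random gene sets below count genes or probe sets. None of these p-values measures the spread between independent groups of flies.

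The deposited values are intensity, linear probe-set signals of a 1-colour array with 1 value per probe set and array. What the authors did to make them is not given in the sources used here. Read from the values, each array was already scaled: the 2% trimmed means of the 12 arrays lay between 1000.12 and 1000.18, within the 10% tolerance written before the data were examined, so the table was used without further normalization. The probe-set names and this scaling are those of Affymetrix MAS 5 signals. Median signals ran from 401.25 to 546.45, and detection calls were not used here, so no probe set was classed as absent. Of 14010 probe sets, 44 controls were left out of the tests and 13966 were tested. A single gene symbol was attached to 12443 of the tested probe sets, several to 327 and none to 1196, and 12394 of the 12443 were matched to current gene names by Entrez number while 49 kept the array's symbol. For gene lists, 10845 genes were each represented by the probe set with the highest mean log2 value.

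The 16 added to each value before the log2 transform damps differences between dim probe sets, so fold changes that involve dim groups are smaller than the ratio of the signals. Probe sets were compared with limma 3.58.1 in R 4.3.3 (lmFit with 4 group means on all 12 arrays, contrasts, eBayes with a mean-variance trend, prior degrees of freedom 4.83). The 5 contrasts are S284Y against WT at 25C and at 30C, 30C against 25C in S284Y and in WT, and the interaction of genotype and temperature. Benjamini-Hochberg adjustment ran over all tested probe sets of a contrast, with a threshold of 0.05. Errors of log2 fold changes are standard errors (SE) of the fit and errors of signals are standard deviations (SD) over 3 arrays. Groups of 3 cannot give an exact permutation p below 0.10, and the number of arrays limits precision.

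Gene lists were written by hand or by symbol pattern before the data were examined: early spliceosome with U2AF, SR and hnRNP proteins, mRNA export and nonsense-mediated decay, heat shock and chaperones with a core of inducible heat-shock genes, genes known to lack introns, antimicrobial and immune genes, Turandot stress genes, detoxification, digestive enzymes, yolk and eggshell, ovary and germline, male accessory gland, testis, photoreceptor, eye pigment, muscle, nervous system, fat body and lipid, glycolysis and TCA cycle, circadian, DNA damage and apoptosis, cell cycle and replication, odorant and taste, cuticle, ribosomal proteins, mitochondrial ribosomal proteins, proteasome, and oxidative phosphorylation. Of 29 lists, 28 had at least 5 measured genes and were tested with limma's camera, once with the preset inter-gene correlation of 0.01 and once with a correlation estimated for each list, adjusted over the lists. A list is said to have moved when its adjusted p with the preset value was under 0.05 and its median went in the direction of the test. Members were counted by the adjustment over all probe sets and by an adjustment over the list alone. After the data were seen, Act57B was taken out of the testis list and His2Av out of the list of genes without introns, because old symbols had pointed to the wrong gene. Exon annotation was not used here, so genes without introns are only the 24 measured members of the hand list, compared with all other genes.

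Genes to name were chosen by a rule written before the data were examined. For each genotype contrast these are the 10 highest and 10 lowest log2 fold changes, and for temperature and interaction the 5 highest and 5 lowest. They had to pass the threshold, carry 1 gene name, have all 3 values of one group above those of the other (not asked of the interaction), and have a mean log2 value of the higher group at or above the 40th percentile, 8.30. A gene with several probe sets is named once, by its brightest. U2af50 and U2af38 are always named, as are up to 4 members with the lowest adjusted p of each list that moved or had 3 or more members past the threshold. Where no gene passed, the 5 lowest unadjusted p-values are named as not passing. Names outside this rule are marked as chosen after their values were seen, except the only measured members of a list too small to test. Effects were also correlated across genes. The neighbours of U2af50 were counted by gene order on assembly Release 6 plus ISO1 MT.

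Alternatives fixed before the data were examined were quantile normalization, median centring, offsets of 1 and 64, leaving out the dimmest 40% of probe sets, eBayes without trend, only the 6 arrays compared, the replicate number as a block, each array left out in turn, the moved WT 30C array, the estimated correlation, the mean of a gene's probe sets, and a comparison of genes without introns with random sets of genes matched on mean value in 20 bins, which gives a permutation p that is not adjusted. Added after the data were seen were leaving out arrays 2 and 3 of S284Y at 25C, limma's array weights, and leaving the 6 lysozymes out of the genes without introns. Other splits of the same arrays were run through the same fit.

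The fit was tested on simulated data that carried the spread of the real residuals and the weights of the real arrays. Of planted 4-fold changes, 54.5% were recovered at 25C and 62.1% at 30C. For 2-fold changes the shares were 20.9% and 25.4%, and for 1.5-fold changes 7.46% and 2.99%. The lower bound asked of the 4-fold recovery was relaxed after the value at 25C was seen, with no change to the fit. In that run 16 of 71 calls at 25C and 2 of 62 at 30C were probe sets with no planted change. Over 10 draws, unchanged probe sets made up 21.8% of calls for genotype at 25C, 0.437% for genotype at 30C, 19.8% for temperature in S284Y and 0.394% for temperature in WT. Without arrays 2 and 3 of S284Y at 25C the shares were 48.4%, 3.37%, 43.4% and 3.55%. All these shares depend on the number and size of the planted changes, and the number differed between comparisons. They are not the share of false calls among the reported genes and cannot be set against each other across comparisons. For temperature in WT, a planted list of 40 genes shifted by 0.5 on the log2 scale was called (adjusted p = 1.2e-32), while 0 of 28 other lists and 0 of 13527 probe sets without a planted change were. Each simulated probe set varied on its own, while real lists had estimated correlations such as 0.560 for male accessory gland. The list result therefore says nothing about false calls of lists whose genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.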

Results

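Signals of gut lysozyme probe sets were far higher, and the small nucleolar RNA host gene Uhg1 was much lower, in S284Y flies at 25C (3 arrays per group). LysC, an enzyme that cuts bacterial cell walls, rose by a log2 fold change of 4.64 ± 0.295 (SE; 24.8-fold, limma adjusted p = 6.4e-06), from a mean signal of 2207 ± 378 (SD) to 59066 ± 30012. Uhg1, whose introns carry small nucleolar RNAs, fell by 5.78 ± 0.352 (adjusted p = 6.4e-06), from 2076 ± 139 to 22.8 ± 10.3. The lower signals of Uhg1 are near the added 16 and not shown to be above background, so the size of its fall depends on the offset (-6.53 with offset 1, -4.63 with offset 64). In all, 110 of 13966 probe sets changed, 44 higher and 66 lower, and 97 of them by over 2-fold. Arrays 2 and 3 of S284Y at 25C stand apart from the other 10, and without them 165 changed, 43 higher and 122 lower. The count was 885 without S284Y 25C array 1, 302 without array 3, and 53, 52 and 48 without WT 25C array 1, 2 and 3. A fit of only the 6 arrays compared gave 17.

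Besides LysC, the lysozymes LysD (4.33, adjusted p = 0.000274), LysB (3.0, adjusted p = 0.00233), LysE (2.97, adjusted p = 0.000425) and LysP (2.84, adjusted p = 0.00172) rose. LysS (0.27, adjusted p = 0.655) and LysX (-0.76, adjusted p = 0.431) did not pass. Over the alternatives the values ran from 3.47 to 4.76 for LysD, 2.19 to 3.4 for LysB and 2.26 to 3.32 for LysE. The probe sets of LysB, LysC, LysD and LysE are of a type that shares sequence within a gene family, so which of these 4 members changed, and how many, is uncertain. Among digestive enzymes, 6 of 49 rose and 2 fell over all genes, and 11 rose and 4 fell when adjusted over the list alone. The others that rose were the serine protease Jon66Ci (3.68 ± 0.639, adjusted p = 0.0171) and the lipase gene mag (1.16), and those that fell were the protease Ser12 (-3.25, adjusted p = 0.00691) and the maltase Mal-A1 (-0.90); mag, Mal-A1, LysS and LysX were chosen after their values were seen. The call of Jon66Ci was lost without S284Y 25C array 2 (adjusted p = 0.0518), without WT 25C array 2 (0.0982) or 3 (0.0922), and without both arrays 2 and 3 of S284Y at 25C (0.182). The digestive list moved up (median 0.17, adjusted p = 0.0174; adjusted p = 0.599 with an estimated correlation). Its median was -0.12 (adjusted p = 0.884) without those 2 arrays, and its call was lost without array 3 alone (adjusted p = 0.648) and under quantile normalization (0.0462, adjusted p = 0.135).

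Detoxification genes changed in both directions at 25C. The cytochrome P450 gene Cyp6a17 (3.72, adjusted p = 0.00563) and the glutathione transferases GstD3 (2.46, adjusted p = 0.00437) and GstE1 (2.33, adjusted p = 0.000792) rose. WT signals of Cyp6a17 (mean 13.4) are near the added 16, so its value depends on the offset (2.48 to 4.74 over the alternatives). Cyp12d1-d (-3.42 ± 0.298, adjusted p = 0.000115), GstE8 (-2.67), GstE6 (-1.74, adjusted p = 0.00322), Cyp6a23 (-1.70) and Cyp6a13 (-1.13) fell, of which GstE8, Cyp6a23 and Cyp6a13 were chosen after their values were seen. That makes 3 higher and 5 lower of 59, against 5 and 13 adjusted over the list alone. The list as a whole did not move (median -0.18, adjusted p = 0.155). Among fat body genes the storage protein Lsp2 (-1.66, adjusted p = 0.00569) and the glycosidase tobi (-1.69, adjusted p = 0.0240) were lower and the desaturase Fad2 (0.97, adjusted p = 0.0131) higher. That is 1 up and 2 down of 31 (1 and 5 adjusted over the list alone). The fat body list moved down (median -0.24, adjusted p = 0.00351; adjusted p = 0.127 with an estimated correlation). Without arrays 2 and 3, which leaves 1 S284Y array, its median was -0.28. Without WT 25C array 1, 2 or 3 the call of tobi was lost (adjusted p = 0.0758, 0.127 and 0.121), and that of Fad2 was lost without array 1 or 3 (0.0796 and 0.0941). Other genes that fell were the mucin-related Mur2B (-4.59, adjusted p = 0.000629), the lipase-family genes CG6277 (-2.92, adjusted p = 0.00558) and CG6283 (-2.88, adjusted p = 0.00330), the serpin Spn77Bb (-2.69, adjusted p = 0.00759; -1.60 by its other probe set), and alpha-Est10 (-3.84, adjusted p = 0.0310). The chitin deacetylase gene Cda9 (-2.83, adjusted p = 0.0171) and Bicra (-2.83, adjusted p = 0.0204) fell too. Acbp2 (2.51, adjusted p = 0.0161) and CG42521 (2.41, adjusted p = 0.0225) rose. The calls of alpha-Est10 (adjusted p = 0.306), Bicra (0.0674), Acbp2 (0.0719) and CG42521 (0.287) were lost without arrays 2 and 3. Over the alternatives the values ran from -4.73 to -2.06 for alpha-Est10, -3.39 to -1.72 for Bicra and 1.57 to 2.83 for CG42521. Leaving out WT 25C array 1 ended those of alpha-Est10 (0.129), Bicra (0.0546), Acbp2 (0.0699) and CG42521 (0.0974). WT 25C array 2 did so for alpha-Est10 (0.122), Bicra (0.109), Acbp2 (0.0970) and Cda9 (0.102), and WT 25C array 3 for alpha-Est10 (0.127), Bicra (0.107), CG42521 (0.123) and Cda9 (0.0643). S284Y 25C array 2 did so for alpha-Est10 (0.0838) and CG42521 (0.0562), and WT 30C array 1, 2 or 3 for alpha-Est10 (0.0599, 0.0582 and 0.0587).

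Genes of ribosomal proteins (median 0.35, adjusted p = 6.4e-05), mitochondrial ribosomal proteins (0.27, adjusted p = 6.4e-05) and oxidative phosphorylation (0.22, adjusted p = 0.00351) lay higher in S284Y at 25C and ovary genes lower (-0.29, adjusted p = 0.0311). In each, 0 members passed, over all genes or adjusted over the list alone. With an estimated correlation the values were adjusted p = 0.599 for the first pair and for ovary, and adjusted p = 0.614 for oxidative phosphorylation. On a scale centred over the arrays, ribosomal protein genes scored 0.74 and 0.59 in arrays 2 and 3 against 0.01 in array 1, and ovary genes -0.22 and -0.47 against 0.03. For the other pair of lists the shift is mostly in array 3: oxidative phosphorylation genes scored 0.83 there against 0.20 and 0.13 in arrays 2 and 1, and mitochondrial ribosomal genes 0.66 against -0.00299 and -0.01. With these arrays left out the medians were -0.02 (adjusted p = 0.913), 0.06 (0.387), 0.00 (0.884) and 0.12 for ovary (0.158). Leaving out array 3 alone ended the calls of mitochondrial ribosomal proteins (adjusted p = 0.525), oxidative phosphorylation (0.817) and ovary (0.680), and array 2 (0.121) or WT 25C array 3 (0.0602) also that of ovary. Under quantile normalization ribosomal proteins (0.06, adjusted p = 0.674) and oxidative phosphorylation (0.09, adjusted p = 0.197) lost theirs, and ovary did with the dimmest 40% left out (0.107). Immune (0.27, adjusted p = 0.0538) and cuticle genes (0.14, adjusted p = 0.0538) did not move, but did in the fit of the 6 arrays (adjusted p = 0.0240 and 0.0362). U2af50 itself did not pass (0.27 ± 0.188, adjusted p = 0.531), nor did its partner U2af38 (0.13, adjusted p = 0.802). The mutation is a single residue that expression cannot check. The simulated shares that follow depend on the planted changes and are not the share of false calls among the genes above. In simulated data 21.8% of calls in this comparison were probe sets without a change, and 48.4% when arrays 2 and 3 were left out.

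**Figure D1:**
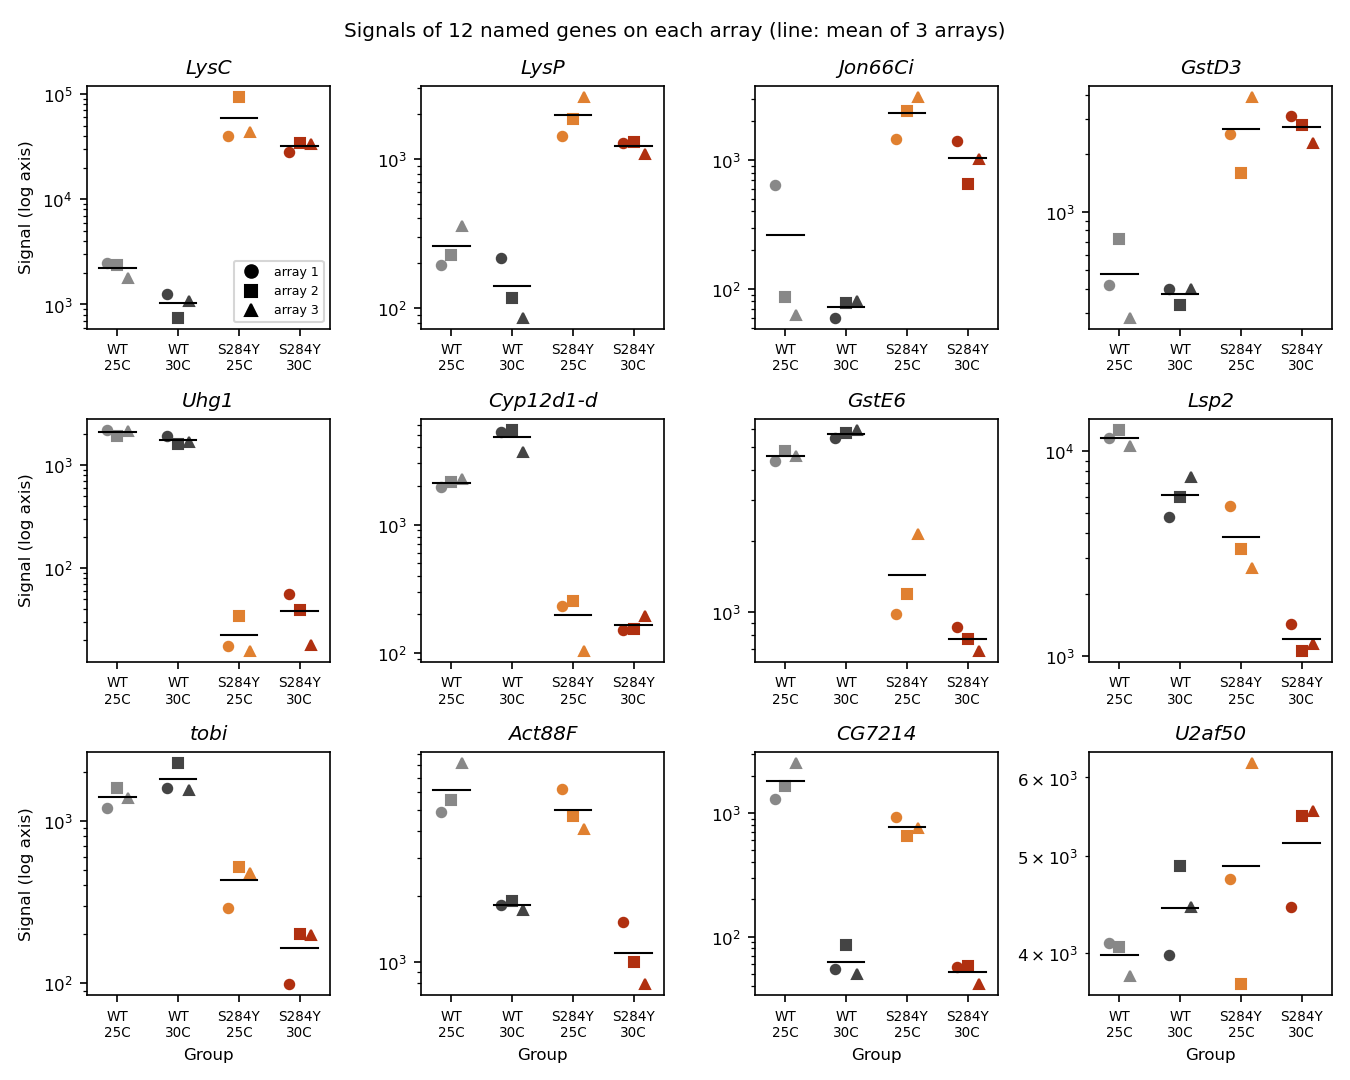
Signal (intensity, log axis) of 12 genes in the 4 groups; each marker is 1 array by replicate number and the line is the mean of 3 arrays. LysC rises from 2207 to 59066 at 25C and Uhg1 falls from 2076 to 22.8.

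At 30C, S284Y flies again had high signals of lysozyme probe sets and low Uhg1, and fat body and detoxification genes lay lower than in WT (3 arrays per group). LysC rose by 4.97 ± 0.295 (31.4-fold, adjusted p = 5.4e-06), from 1024 ± 250 to 32116 ± 3230, and Uhg1 fell by 5.07 ± 0.352 (adjusted p = 7.4e-06; -5.60 with offset 1 and -4.15 with offset 64). The P450 gene Cyp12d1-d fell by 4.71 ± 0.298 (26.2-fold, adjusted p = 6.1e-06) and tobi, a target of brain insulin signalling, by 3.35 ± 0.314 (adjusted p = 0.00012). Of 13966 probe sets 213 changed, 49 higher and 164 lower, 186 of them by over 2-fold. Arrays 2 and 3 of S284Y at 25C are not in this comparison but widen the pooled spread. Without them 1278 changed, 538 higher and 740 lower, and the 6 arrays compared alone gave 1106. The count was 821 without S284Y 25C array 3 and 328 without array 2. It was 87, 91 and 108 without WT 30C array 1, 2 and 3, 101 and 82 without S284Y 30C array 2 and 3, and 106 with WT 30C array 1 moved to 25C.

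Fat body and lipid genes fell at 30C, 8 of 31 with 0 higher over all genes and 15 lower with 1 higher adjusted over the list alone. Lsp2 (-2.30 ± 0.247, adjusted p = 0.000378), the lipid droplet protein Lsd-1 (-1.57, adjusted p = 0.00559), Obp99b (-2.13, adjusted p = 0.00904) and tobi had the lowest adjusted p. The fatty acid synthase FASN1 (-1.20, adjusted p = 0.0280), Pepck1 of gluconeogenesis (-0.99), Lip3 (-2.29) and fat-spondin (-0.93) were the rest, chosen after their values were seen. The list moved down (median -0.60, adjusted p = 5.0e-10) and kept its call with an estimated correlation (adjusted p = 0.00166). The call of Obp99b was lost without WT 30C array 2 (adjusted p = 0.0583) or 3 (0.0618). Detoxification genes moved down as well (median -0.34, adjusted p = 2.2e-05; adjusted p = 0.00489 with an estimated correlation). Of 59, 10 were lower and 3 higher, and 16 and 3 adjusted over the list alone. Cyp12d1-d, Cyp6a13 (-2.81, adjusted p = 2.1e-05), Cyp6a8 (-3.13, adjusted p = 0.000421), Cyp6g1 (-0.99) and Cyp12a4 (-1.16) fell. So did GstE6 (-2.86, adjusted p = 4.0e-05), GstE7 (-3.86, adjusted p = 0.00281), GstE8 (-3.79, adjusted p = 0.000317), GstE9 (-1.11) and GstE5 (-1.34). Signals of GstE7 in S284Y (mean 21.1) are near the added 16, and its value ran from -4.72 to -2.74 over the alternatives. The 3 that rose were Cyp6a17 (3.19, adjusted p = 0.00946), GstD3 (2.81, adjusted p = 0.000877) and GstE1 (2.19, adjusted p = 0.000694). Cyp6a17, dim in WT (mean 35.6), ran from 2.16 to 4.08 over the alternatives. Cyp6g1, Cyp12a4, GstE9, GstE5 and GstE1 were chosen after their values were seen. In the fit without arrays 2 and 3 of S284Y at 25C, 17 fat body genes were lower and 2 higher, and 17 detoxification genes lower and 5 higher. The call of Cyp6a17 was lost without WT 30C array 1 (0.0674) or 3 (0.0618) or S284Y 30C array 3 (0.0563).

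Digestive enzymes changed in both directions at 30C: 8 of 49 fell and 5 rose, 17 and 8 adjusted over the list alone. The maltases Mal-A1 (-1.50, adjusted p = 0.000508), Mal-A6 (-1.95), Mal-A8 (-2.01), Mal-B1 (-2.83) and Mal-B2 (-2.22) and the proteases thetaTry (-0.86), Jon25Bi (-1.59) and Jon44E (-1.53) fell, all but Mal-A1 chosen after their values were seen. Mal-B1 in S284Y, with a mean signal of 18.9, is at the level of the added 16. LysD (4.24, adjusted p = 0.000214), LysP (3.07, adjusted p = 0.000508), LysB (2.88, adjusted p = 0.0016), LysE (2.70, adjusted p = 0.000508) and Jon66Ci (3.5, adjusted p = 0.0138) rose. LysS (-0.51, adjusted p = 0.533) and LysX (0.02, adjusted p = 0.994), also chosen after, did not pass. The list moved down (median -0.60, adjusted p = 0.000958; adjusted p = 0.459 with an estimated correlation). In the fit without arrays 2 and 3 of S284Y at 25C, 20 were lower and 9 higher. The call of Jon66Ci was lost without WT 30C array 1 (adjusted p = 0.0730), 2 (0.0644) or 3 (0.0567) and without S284Y 30C array 1 (0.0667) or 3 (0.0709). Naa80, which acetylates actin (2.55, adjusted p = 0.000317), rose. The talin gene rhea did so by 1 probe set (2.43, adjusted p = 8.9e-05) but not by its other (-0.03). Further genes that fell were Mur2B (-4.13, adjusted p = 0.00072), the lysosomal mannosidase gene LManVI (-4.09, adjusted p = 0.00726; 0.0512 without S284Y 30C array 3), the esterase alpha-Est2 (-3.70, adjusted p = 0.00414; -4.30 to -2.75 over the alternatives, with a mean signal of 30.1 in S284Y) and Cyp4e3 (-3.26, adjusted p = 0.000576). The cuticle gene Cpr47Ef rose (1.98, adjusted p = 0.0477; chosen after its value was seen).

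Cell cycle and replication genes lay higher in S284Y at 30C, 31 of 33 with a positive value (median 0.41, adjusted p = 6.3e-06; adjusted p = 0.459 with an estimated correlation). Over all genes or adjusted over the list alone, 0 members passed. Among them, Prim1 (1.04) and PolA2 (0.94, adjusted p = 0.125), both of the primase complex, did not pass. Once arrays 2 and 3 of S284Y at 25C were left out, 15 cell cycle genes passed, all higher, and 12 did so in the fit of the 6 arrays. Early spliceosome genes also lay higher (0.14, adjusted p = 0.020; adjusted p = 0.158 with an estimated correlation; 0 of 17 passing). Phf5a had the lowest adjusted p among them without passing (0.71, adjusted p = 0.233), and leaving out WT 30C array 3 ended the list's call (adjusted p = 0.0505). Smaller upward shifts of ribosomal proteins (0.13, adjusted p = 0.0180; 0 of 33, with RpL28 at 1.36 not passing) and the proteasome (0.14, adjusted p = 0.0491; 0 of 39) had adjusted p = 0.650 and adjusted p = 0.158 with an estimated correlation. Oxidative phosphorylation (-0.25, adjusted p = 0.000124; 0 of 69), yolk and eggshell (-0.38, adjusted p = 0.020) and testis genes (-0.28, adjusted p = 0.0394; 0 of 47) lay lower, with adjusted p = 0.576, 0.576 and 0.362 with an estimated correlation. In the eggshell list 1 of 22 passed, the eggshell gene Femcoat (-1.15, adjusted p = 0.0117). Adjusted over the list alone 8 were lower and 1 higher, the yolk protein gene Yp1 (2.08, chosen after its value was seen). Without arrays 2 and 3 of S284Y at 25C, which only narrows the spread, members that passed were 9 lower of oxidative phosphorylation, 9 lower and 2 higher of eggshell, 7 lower and 1 higher of testis, 3 higher and 1 lower of ribosomal protein and 4 higher of proteasome genes. Ovary genes did not move (0.16, adjusted p = 0.0586; adjusted p = 0.584 with an estimated correlation), but did without arrays 2 and 3 (adjusted p = 0.00528; 9 higher and 1 lower) and in the fit of the 6 arrays (0.00615). Leaving out WT 30C array 1 ended the calls of Femcoat (0.0768), ribosomal proteins (0.113) and testis (0.0820). WT 30C array 2 did so for Femcoat (0.0737), testis (0.0630) and proteasome (0.0630), and WT 30C array 3 for eggshell (0.0727) and proteasome (0.119). S284Y 30C array 2 ended those of Femcoat (0.0708), ribosomal proteins (0.0792), testis (0.0604) and proteasome (0.0963). S284Y 30C array 3 ended those of Femcoat (0.0680), eggshell (0.0531), oxidative phosphorylation (0.0531), testis (0.210) and proteasome (0.0788). S284Y 25C array 2 ended those of eggshell (0.0759) and proteasome (0.0609), and WT 25C array 1, 2 or 3 that of proteasome (0.0571, 0.0578 and 0.0537). Ribosomal proteins turned to -0.03 under quantile normalization (adjusted p = 0.942). Median centring ended the calls of testis and proteasome (adjusted p = 0.0544 each), and moving WT 30C array 1 to 25C those of testis (0.0668) and ribosomal proteins (0.204). For proteasome, offset 64 (0.0520), eBayes without trend (0.0761) and the replicate block (0.0626) did so too. Of 115 odorant and taste genes 3 fell, Obp99b, Obp18a (-0.97, adjusted p = 0.0453) and Obp83cd (-1.60, adjusted p = 0.0493). The last pair lost their calls without any 1 of the 9 arrays outside S284Y at 25C, and the list did not move (median -0.15, adjusted p = 0.418). U2af50 (0.21, adjusted p = 0.802) and U2af38 (0.05, adjusted p = 0.972) did not pass.

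**Figure D2:**
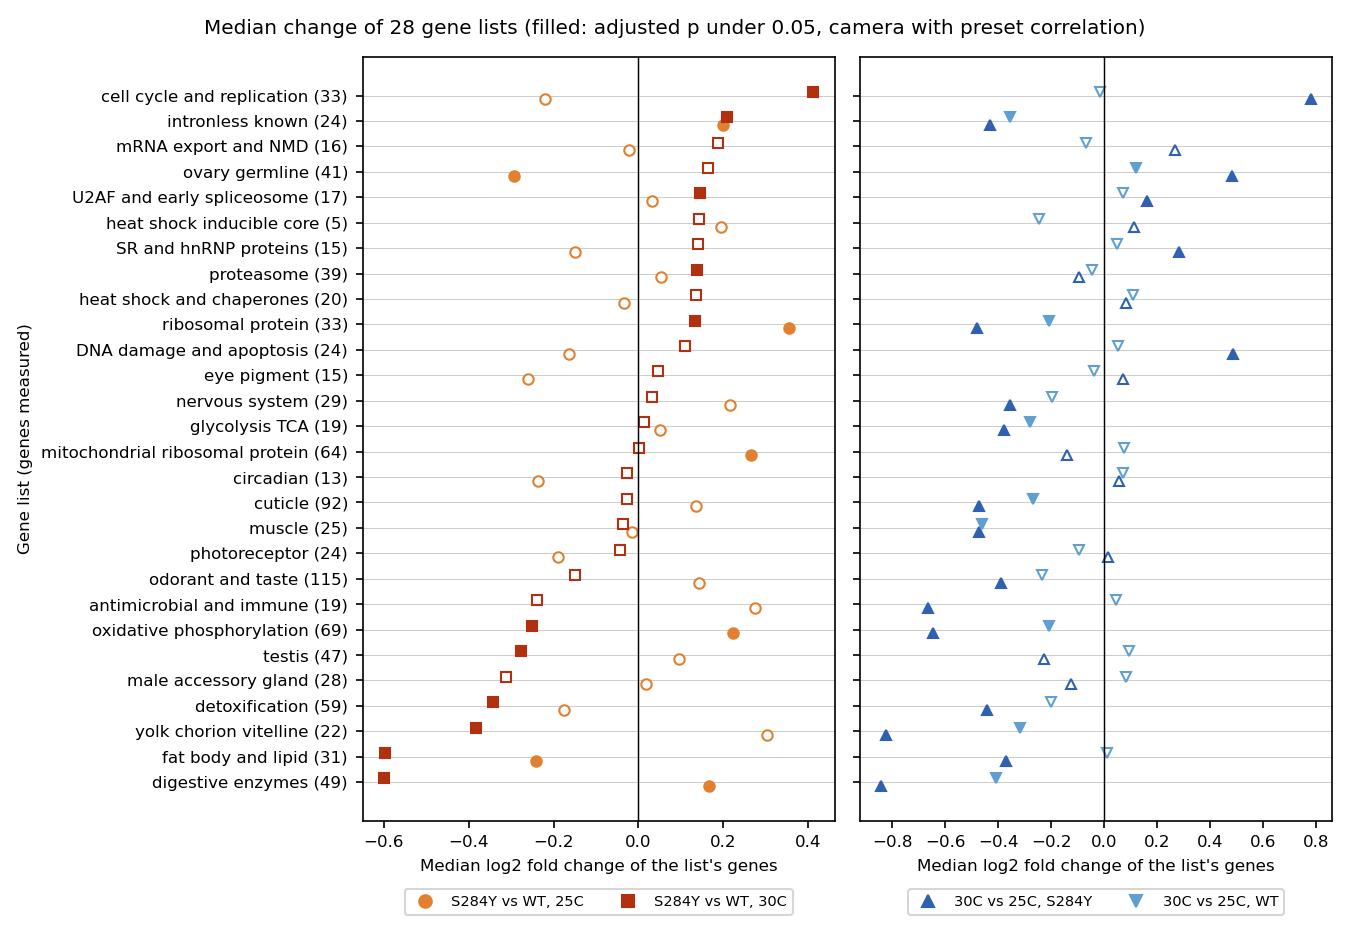
Median log2 fold change of 28 gene lists (genes measured in parentheses), left for S284Y against WT at 25C and 30C, right for 30C against 25C in S284Y and WT; filled markers are lists that moved. Fat body genes lie at -0.60 and cell cycle genes at 0.41 in S284Y at 30C.

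The genotype differences were partly shared between 25C and 30C, comparisons that have no array in common. Of the probe sets higher in S284Y, 44 at 25C and 49 at 30C, 21 were the same (0.154 expected if calls were independent), and of the 66 and 164 lower ones 38 were (0.775 expected). The expected counts in this paragraph can be too low because both comparisons use the same spread. LysB, LysC, LysD, LysE, LysP, Cyp6a17, GstD3, Uhg1, Mur2B and Cyp12d1-d are among them. Of the 164 lower at 30C, 152 had the same sign at 25C, and of the 49 higher ones 41 did. Across 10845 genes the effects at 25C and 30C had a Pearson correlation of 0.267 (Spearman 0.147). The Pearson value was 0.337 without arrays 2 and 3 of S284Y at 25C, when 33 higher and 84 lower probe sets were shared (1.66 and 6.46 expected).

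In S284Y flies at 30C against 25C, muscle, digestive and oxidative phosphorylation lists moved down and the ovary list up with the preset correlation (3 arrays per group). With an estimated correlation these lists had adjusted p = 0.110, 0.0828, 0.137 and 0.137. The flight muscle actin gene Act88F fell by 2.19 ± 0.255 (adjusted p = 0.00307), the gut protease gene Jon25Bii by 1.90 (adjusted p = 0.00207), and CG7214 by 3.54 ± 0.349 (11.6-fold, adjusted p = 0.00132). In all 559 of 13966 probe sets changed, 254 higher and 305 lower, 384 of them by over 2-fold. Under median centring 321 were higher and 239 lower, so the balance of directions depends on the scaling. Arrays 2 and 3 of S284Y at 25C weigh on this comparison: without them 183 changed, 70 higher and 113 lower, and the fit of the 6 arrays alone called 0. The count was 2398 without S284Y 25C array 1 and 1026 without array 3, 134, 31 and 17 without S284Y 30C array 1, 2 and 3. It was 219, 212 and 201 without WT 25C array 1, 2 and 3, 195, 135 and 184 without WT 30C array 1, 2 and 3, and 222 with WT 30C array 1 moved to 25C. The simulated shares that follow depend on the planted changes and are not the share of false calls among these probe sets. In simulated data 19.8% of calls in this comparison were probe sets without a change, and 43.4% without arrays 2 and 3.

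Muscle genes fell, 5 of 25 (7 adjusted over the list alone; 8 without arrays 2 and 3): Act88F, the myosin light chains Mlc2 (-1.24, adjusted p = 0.00911) and Mlc1 (-1.53, adjusted p = 0.0102), flightin gene fln (-1.85, adjusted p = 0.0207) and the arginine kinase Argk1 (-0.67; chosen after its value was seen). The list moved down (median -0.47, adjusted p = 3.0e-06; adjusted p = 0.110 with an estimated correlation). Digestive enzymes fell in 12 of 49 (27 adjusted over the list alone; 9 without arrays 2 and 3), among them lambdaTry (-1.43, adjusted p = 0.00726), Jon99Fi (-1.67, adjusted p = 0.0102) and Jon44E (-1.77, adjusted p = 0.0102). Their list moved down (-0.84, adjusted p = 3.8e-14; adjusted p = 0.0828 with an estimated correlation). Oxidative phosphorylation genes fell in 15 of 69 (40 adjusted over the list alone; 4 without arrays 2 and 3), with ATPsynO (-0.88, adjusted p = 0.0241) and ATPsyngamma (-0.74, adjusted p = 0.0271) of the ATP synthase, ATPsynF (-0.96) and the complex I gene ND-B8 (-1.31). This list moved down too (-0.65, adjusted p = 2.1e-14; adjusted p = 0.137 with an estimated correlation). Detoxification genes fell in 8 of 59 (9 adjusted over the list alone), with GstE9 (-1.30, adjusted p = 0.00789), Cyp6a13 (-1.29), Cyp6a8 (-1.90) and GstE3 (-0.95). This list kept its call with an estimated correlation (median -0.44, adjusted p = 0.000109; adjusted p = 0.0227 with an estimated correlation). Fat body genes fell in 3 of 31 (6 adjusted over the list alone), Lsp2 (-1.59, adjusted p = 0.0102), tobi (-1.31) and Men (-0.72), and the list moved down. Its median was -0.37 (adjusted p = 0.00492; adjusted p = 0.0828 with an estimated correlation). Without S284Y 30C array 3 the calls of Mlc1, Mlc2, fln, lambdaTry, Jon99Fi, Jon44E, ATPsynO, ATPsyngamma, ATPsynF, ND-B8, GstE9, Cyp6a13, Cyp6a8, GstE3, Lsp2, tobi and Men were lost (adjusted p from 0.0505 for lambdaTry to 0.131 for Men). Leaving out array 2 ended those of all but Mlc1, lambdaTry and GstE9 (from 0.0511 for Cyp6a8 to 0.144 for Men). Without S284Y 30C array 1 those of ATPsynO (0.0524), ATPsyngamma (0.0588), ATPsynF (0.0661), ND-B8 (0.0645), tobi (0.110) and Men (0.104) were lost. WT 30C array 2 left out ended those of ATPsyngamma (0.0516), ATPsynF and ND-B8 (0.0503 each). The genes tobi and Men lost theirs without any 1 of the 6 WT arrays or S284Y 25C array 2 (from 0.0531 to 0.0736).

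Ovary and germline genes rose in 7 of 41 (10 adjusted over the list alone; 3 without arrays 2 and 3), among them aub and krimp of the piRNA pathway (1.20, adjusted p = 0.0182, and 2.01), the germ plasm gene osk (1.19, adjusted p = 0.0315) and ovo by its brighter probe set (1.02; -0.07 by the other). Their list moved up (0.48, adjusted p = 1.5e-06; adjusted p = 0.137 with an estimated correlation), and by 0.23 without arrays 2 and 3. Over the alternatives krimp ran from 0.85 to 2.60 and twe, a cell cycle gene, from 0.65 to 1.72. Cell cycle genes were higher in 33 of 33 (median 0.78, adjusted p = 2.7e-08; adjusted p = 0.163 with an estimated correlation). CycD (0.90, adjusted p = 0.0419) and the phosphatase gene twe (1.36, adjusted p = 0.0461) passed, and 9 did adjusted over the list alone. Array 3 of S284Y at 25C carries most of this: cell cycle genes scored -1.11 there against 0.08 and 0.06 in arrays 1 and 2. With arrays 2 and 3 left out, which leaves 1 array at 25C, the median was 0.33. Among splicing genes the polypyrimidine tract binding protein gene heph (1.31, adjusted p = 0.0269; -0.07 by its other probe set), glo (1.06, adjusted p = 0.0435) and Sf3a1 (0.95, adjusted p = 0.0384) rose. SR and hnRNP proteins (0.28, adjusted p = 0.0173; 2 of 15, or 3 higher and 1 lower adjusted over the list alone) and early spliceosome genes (0.16, adjusted p = 0.0217; 1 of 17) moved up, with adjusted p = 0.162 and 0.137 with an estimated correlation. Leaving out arrays 2 and 3 the values were 0.15 (adjusted p = 0.235) and 0.16 (adjusted p = 0.0496). With the dimmest 40% left out neither list kept its call (0.0746 and 0.0954), and early spliceosome genes lost theirs under quantile normalization (0.0557). U2af50 (0.10, adjusted p = 0.768) and U2af38 (-0.16, adjusted p = 0.665) did not pass. Without S284Y 30C array 2 or 3 the calls of aub (0.0731 and 0.0955), krimp (0.108 and 0.122), osk (0.107 and 0.121), ovo (0.114 and 0.122), heph (0.0955 and 0.121), CycD (0.126 and 0.141), twe (0.105 and 0.176), glo (0.123 and 0.157) and Sf3a1 (0.135 and 0.121) were lost. Without S284Y 30C array 1 or any 1 of the 6 WT arrays those of krimp, osk, ovo, CycD, twe, glo and Sf3a1 were lost as well (from 0.0514 for ovo to 0.0986 for CycD). S284Y 25C array 2 left out ended those of CycD (0.0616), twe (0.0577), glo (0.0550) and Sf3a1 (0.0538). The call of heph was also lost without S284Y 30C array 1 (0.0645) or WT 30C array 2 (0.0503). DNA damage genes moved up with 0 of 24 passing (0.49, adjusted p = 0.0207; adjusted p = 0.238 with an estimated correlation), and not without S284Y 25C array 3 (adjusted p = 0.0895) or without arrays 2 and 3 (0.12, adjusted p = 0.501). SR and hnRNP proteins lost their call without S284Y 25C array 2 (adjusted p = 0.0970).

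Eggshell genes fell in 4 of 22 (12 adjusted over the list alone), Femcoat (-1.19, adjusted p = 0.0162), Vm26Ac (-1.29, adjusted p = 0.0172), Cp19 (-1.27) and Vm32E (-1.24), although other ovary genes rose. The list moved down (-0.82, adjusted p = 3.0e-06; adjusted p = 0.148 with an estimated correlation). Leaving out arrays 2 and 3 its median was -0.25 with 1 member passing; it scored 0.88 in array 2 against 0.06 in array 1. Cuticle genes fell in 7 of 92 (7 adjusted over the list alone), among them Ccp84Ae (-1.49, adjusted p = 0.0102), Cpr49Ae (-1.74), Cpr49Ab (-1.35) and Acp65Aa (-2.41), with the list at -0.47 (adjusted p = 4.6e-05; adjusted p = 0.110 with an estimated correlation), and at -0.25 with 3 passing when arrays 2 and 3 were left out. Glycolysis and TCA genes moved down (-0.38, adjusted p = 0.000884; adjusted p = 0.137 with an estimated correlation), 2 of 19 passing, SdhC (-0.89, adjusted p = 0.0403) and Gapdh1 (-0.95, adjusted p = 0.0440). There were 8 lower and 1 higher adjusted over the list alone. Odorant and taste genes moved down (-0.39, adjusted p = 0.00449; adjusted p = 0.137 with an estimated correlation), with Obp18a (-1.12), Obp57c (-1.33), Obp99c (-1.16) and Obp99a (-1.18; chosen after its value was seen) falling and Obp99d (2.15, adjusted p = 0.0440) rising. Immune genes moved down (-0.67, adjusted p = 0.0374; adjusted p = 0.137 with an estimated correlation) with Drsl5 (-1.87, adjusted p = 0.0260), PGRP-LB (-1.06, adjusted p = 0.0260) and the serpin gene nec (-0.70, adjusted p = 0.0293) falling. That is 3 of 19, and 7 lower and 2 higher adjusted over the list alone. Ribosomal protein (-0.48, adjusted p = 0.000109; 0 of 33) and nervous system genes (-0.36, adjusted p = 0.0396; 0 of 29) moved down with 0 passing (adjusted p = 0.332 and 0.151 with an estimated correlation). Leaving out arrays 2 and 3 ended the calls of odorant and taste (-0.19, adjusted p = 0.155), immune (-0.14, adjusted p = 0.227), ribosomal (-0.10, adjusted p = 0.468) and nervous system genes (-0.14, adjusted p = 0.0643). Quantile normalization ended those of ribosomal protein (-0.00733, adjusted p = 0.940), glycolysis (-0.0957, adjusted p = 0.0556), odorant and taste (-0.29, adjusted p = 0.0552) and nervous system genes (0.0696). Immune genes lost theirs under median centring (0.0578) and eBayes without trend (0.0611). Single arrays ended those of immune genes (S284Y 25C array 2, 0.0643, or 3, 0.0823; S284Y 30C array 2, 0.0516). They ended that of nervous system genes (S284Y 25C array 1, 0.0815, or 2, 0.126; S284Y 30C array 1, 0.0682, or 3, 0.0514). The Hedgehog co-receptor gene ihog (2.90 ± 0.454, adjusted p = 0.0104), Cul6 (2.77, adjusted p = 0.0157), CG10462 (2.69, adjusted p = 0.0268), rno (2.65, adjusted p = 0.0396) and CG4496 (2.49, adjusted p = 0.0162) had the largest rises. Their sizes depend on arrays 2 and 3: over the alternatives they ran from 1.97 to 3.37 for ihog, 1.63 to 3.33 for Cul6, 1.84 to 3.22 for CG10462, 0.91 to 3.52 for rno and 1.61 to 2.93 for CG4496. Below CG7214 the largest falls were those of LManIII (-3.15, adjusted p = 0.00726), CG1304 (-2.89, adjusted p = 0.00655), CG13315 (-2.62, adjusted p = 0.00273) and CG15422 (-2.56, adjusted p = 0.0431). The ranges were -3.92 to -2.17 for LManIII, dim at 30C (mean 32.6), -3.18 to -1.32 for CG15422, and 1.22 to 2.98 for Obp99d, whose mean of 14.3 at 25C is at the level of the added 16. Of all genes whose calls were followed with single arrays left out, Act88F, Jon25Bii, CG7214, CG1304 and CG13315 kept theirs throughout. Each of the others among these lists and largest changes lost its call without S284Y 30C array 3 (adjusted p from 0.0505 for LManIII to 0.155 for CG15422). Most also lost it without S284Y 30C array 2 (from 0.0511 for Ccp84Ae to 0.134 for Gapdh1). SdhC, Gapdh1, Obp99c, nec, rno and CG15422 lost it without any 1 of the 6 WT arrays (from 0.0511 for nec to 0.0727 for Gapdh1).

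In WT flies, 30C against 25C lowered CG7214 and the flight muscle actin Act88F, and how many other genes were called depended on the arrays that set the spread (3 arrays per group). CG7214 fell by 4.51 ± 0.349 (22.9-fold, adjusted p = 0.000138), from 1819 ± 630 to 62.7 ± 19.1, and Act88F by 1.72 ± 0.255 (adjusted p = 0.0284), from 6177 ± 1727 to 1822 ± 86.3. The juvenile hormone binding protein gene Jhbp3 (-1.31, adjusted p = 0.00704), the metallothionein MtnB (-1.93, adjusted p = 0.0282) and CG4440 (-3.14, adjusted p = 0.0284) fell. The clock gene tim (1.82 ± 0.257, adjusted p = 0.0282; -0.51 and -0.33 by its other probe sets), GstD9 (1.57, adjusted p = 0.0455), CG4570 (1.27, adjusted p = 0.0205) and the RNA helicase gene Ddx56 (1.02, adjusted p = 0.0297) rose. Of 13966 probe sets 13 changed, 4 higher and 9 lower. Without arrays 2 and 3 of S284Y at 25C 200 did, 92 higher and 108 lower, and the 6 WT arrays alone gave 178. With WT 30C array 1 moved to 25C, as its description reads, 0 changed and adjusted p rose to 1.0 for each of these 9 genes. Over all probe sets, however, the 3 WT 30C arrays correlated with each other at 0.954 to 0.959. No WT 25C array correlated with any other array above 0.947. These values argue against array 1 being a 25C sample and go with its title. The count of changed probe sets was 99 without S284Y 25C array 3, 3, 3 and 8 without S284Y 30C array 1, 2 and 3, 1 without each of WT 25C array 1, 2 and 3, and 2, 1 and 1 without WT 30C array 1, 2 and 3. Only the call of CG7214 outlasted the loss of every single array, and that of Act88F was lost without any 1 of the 6 WT arrays (adjusted p from 0.0994 to 0.185).

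Muscle genes as a group moved down in WT at 30C, 25 of 25 below 0 (median -0.46, adjusted p = 1.3e-15), and kept the call with an estimated correlation (adjusted p = 0.0329). Of the 25 only Act88F passed over all genes, but 9 did adjusted over the list alone and 10 over all genes without arrays 2 and 3 of S284Y at 25C. The 9 include Mlc1, Mlc2 and fln (chosen after its value was seen), which also fell in S284Y. Glycolysis (-0.28, adjusted p = 4.8e-05), oxidative phosphorylation (-0.21, adjusted p = 4.8e-05), digestive (-0.41, adjusted p = 7.7e-05), ribosomal protein (-0.21, adjusted p = 0.000189), cuticle (-0.27, adjusted p = 0.000839) and eggshell genes (-0.32, adjusted p = 0.0157) moved down with 0 passing. With an estimated correlation these had adjusted p = 0.203, 0.457, 0.419, 0.457, 0.203 and 0.457. Adjusted over the list alone, ATPsynC (-0.87), Mal-A3 (-2.25), lambdaTry (-0.93), RpL17 (-1.68), RpL37A (-1.77), RpLP1 (-0.93), Cpr49Ae (-1.58), Cpr47Ef (-2.33) and Cpr78Ca (-1.79) were lower. Ovary genes moved up (0.12, adjusted p = 0.0246; adjusted p = 0.457 with an estimated correlation). Odorant and taste genes did not move (-0.23, adjusted p = 0.0548), but did without arrays 2 and 3 (adjusted p = 0.0307) and in the 6 WT arrays alone (0.0432). Ribosomal proteins turned to 0.13 under quantile normalization. Eggshell genes lost their call without WT 25C array 2 (adjusted p = 0.125) or WT 30C array 2 (0.0756), and ovary genes without WT 25C array 2 (0.0643) or WT 30C array 1 (0.0570) or 2 (0.0622). With WT 30C array 1 moved to 25C, eggshell (0.0616), ovary (0.194), cuticle (0.108) and ribosomal protein genes (0.326) lost theirs. So did eggshell genes under quantile normalization (-0.12, adjusted p = 0.216) and ovary genes with the dimmest 40% left out (0.115). With the mean of a gene's probe sets the ovary median was 0.06 and its call was lost too (adjusted p = 0.0776). U2af50 (0.15, adjusted p = 0.962) and U2af38 (-0.08, adjusted p = 0.984) did not pass.

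The temperature effects had features in common across genotypes: 5 of the 9 probe sets lower in WT and 3 of the 4 higher ones were called in S284Y too, CG7214 and Act88F among them. If calls were independent 0.197 and 0.0727 were expected, which can be too low because both comparisons use the same spread. In the fit without arrays 2 and 3 of S284Y at 25C, 34 lower and 17 higher probe sets were shared (0.874 and 0.461 expected). Of the 305 lower in S284Y 264 had the same sign in WT, and of the 254 higher ones 228 did. Across 10845 genes the effects correlated at 0.327 (Spearman 0.362), with no array in common.

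For the interaction, the test of whether the genotype effect differs between temperatures, limma called 0 probe sets, with 1127 at unadjusted p below 0.05, and 0 without arrays 2 and 3 or with array weights. Without S284Y 25C array 1, which leaves only the arrays that stand apart in that group, 84 were called. The lowest p-values, none passing, belonged to CG42288 (-2.19, adjusted p = 0.147), the glycine methyltransferase gene Gnmt (-2.28, adjusted p = 0.147), CG11666 (-2.75, adjusted p = 0.203), Cyp6a13 (-1.68, adjusted p = 0.263) and the Hippo kinase gene wts (2.34, adjusted p = 0.263). U2af50 (-0.05) and U2af38 (-0.08) did not pass. As groups, cell cycle (0.63, adjusted p = 2.3e-08), ovary (0.35, adjusted p = 0.000586) and SR and hnRNP genes (0.34, adjusted p = 0.0330) had a more positive genotype effect at 30C. Oxidative phosphorylation (-0.46, adjusted p = 2.3e-08), digestive (-0.55, adjusted p = 2.3e-08), eggshell (-0.37, adjusted p = 0.00117), fat body (-0.37, adjusted p = 0.00223), mitochondrial ribosomal (-0.25, adjusted p = 0.00268), detoxification (-0.21, adjusted p = 0.00613), testis (-0.37, adjusted p = 0.0109) and immune genes (-0.54, adjusted p = 0.0326) had a more negative one. With an estimated correlation none of the 11 kept its call: adjusted p = 0.0609 for fat body and detoxification, 0.224 for digestive and immune, 0.288 for testis, 0.332 for cell cycle, ovary, SR and hnRNP, oxidative phosphorylation and eggshell, and 0.491 for mitochondrial ribosomal genes. Adjusted over the list alone, 5 digestive, 2 eggshell and 1 detoxification genes were lower and 0 higher. SR and hnRNP genes lost their call with the dimmest 40% left out (adjusted p = 0.0941). Array weights ended those of immune (0.0804) and mitochondrial ribosomal genes (0.166). The eggshell median ran from -0.56 to -0.03 over the alternatives. Leaving out arrays 2 and 3 leaves 1 array for S284Y at 25C, so this fit has no replicates in that group. Its medians were -0.28 for fat body, -0.20 for oxidative phosphorylation, 0.26 for cell cycle, -0.35 for digestive, -0.25 for detoxification and -0.18 for testis genes. For ribosomal proteins the median was 0.15, against -0.19 (adjusted p = 0.178) with all arrays. Ovary (0.10), eggshell (-0.28), mitochondrial ribosomal (-0.07), immune (-0.21) and SR and hnRNP genes (0.00) lost their calls in it.

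Known intronless genes lay above other genes in S284Y by a median of 0.21 at 25C (24 genes, adjusted p = 0.00234) and 0.19 at 30C (adjusted p = 0.00189), with adjusted p = 0.286 and 0.158 with an estimated correlation. The difference at 25C was 0.10 without WT 25C array 3 and 0.38 without WT 25C array 2. With single arrays left out its adjusted p stayed at or below 0.0107. The only members that passed at either temperature were the lysozymes LysB, LysD, LysE and LysP, the first 3 by probe sets that share sequence, 4 higher and 0 lower of 24 (5 and 4 higher adjusted over the list alone, the fifth at 25C being the antifungal peptide gene Drs, 1.05, chosen after its value was seen). With the 6 lysozymes out, the differences were 0.07 (adjusted p = 0.344) and 0.15 (adjusted p = 0.434). Against genes matched on mean value they were 0.12 and 0.20, with p = 0.308 and 0.0406 by permutation over random gene sets and not adjusted. At 30C against 25C the same genes lay lower in S284Y (-0.38, adjusted p = 0.0261; 0.162 with an estimated correlation) and in WT (-0.35, adjusted p = 0.00300; 0.203 with an estimated correlation), with only LysS passing in S284Y (-1.13, adjusted p = 0.0387) and 0 in WT. In the fits of the 6 arrays compared 0 of 24 passed in S284Y, LysS included, and 2 were lower in WT. Without the lysozymes these were -0.25 (adjusted p = 0.224) and -0.26 (adjusted p = 0.142). Matched on mean value they were -0.24 and -0.29, with permutation p = 0.118 and 0.0038, not adjusted. The value in S284Y was -0.09 (adjusted p = 0.184) under quantile normalization and lost its call without S284Y 25C array 2 (adjusted p = 0.0694) or 3 (0.0518) or S284Y 30C array 2 (0.0593). The value in WT lost it without WT 25C array 2 (0.0539). Leaving out arrays 2 and 3 of S284Y at 25C, the genotype difference at 25C was 0.10 (adjusted p = 0.0562) and the temperature difference in S284Y -0.16 (adjusted p = 0.418). The interaction was -0.04 (adjusted p = 0.788).

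With all arrays heat-shock genes did not move in any comparison: chaperones (20 genes) had a median of 0.11 and the inducible core (5 genes) of -0.25 at 30C against 25C in WT, and 0.08 and 0.11 in S284Y. Chaperones moved up in S284Y once arrays 2 and 3 at 25C were left out (0.12, adjusted p = 0.0338; with all arrays and an estimated correlation adjusted p = 0.151), and 2 of them passed as higher in the fit of the 6 WT arrays. In S284Y Hsf was the only member to rise (0.71, adjusted p = 0.0428; chosen after its value was seen). Genes of mRNA export and nonsense-mediated decay (16 genes; 0.19), male accessory gland (28 genes; -0.31) and photoreceptor (24 genes; -0.04) did not move between genotypes at 30C, nor did eye pigment (15 genes; 0.05) or circadian genes (13 genes; -0.03). Male accessory gland genes did move down in the fit of the 6 arrays (adjusted p = 0.0384) and without arrays 2 and 3 (0.0372), and in the latter at 25C too (-0.42, adjusted p = 0.0458, from 1 S284Y array; 0.02, adjusted p = 0.777 with all arrays). With all arrays and an estimated correlation the values were adjusted p = 0.788 at 30C and 0.923 at 25C. In S284Y at 30C against 25C the eye pigment genes pr (0.95, adjusted p = 0.0282), st (-1.37) and Pu (-1.22) changed in opposite directions. None of these calls held in the fit of the 6 arrays compared, where 0 of 15 eye pigment genes passed. Of the Turandot stress genes only TotE and TotB were measured, too few to test, with medians of 0.18 and -0.71 between genotypes at 25C and 30C, -0.81 and 0.08 between temperatures in S284Y and WT, and -0.89 for the interaction. For immune genes between genotypes at 30C the median was -0.24 and the mean 0.01 with the test pointing down, and for proteasome genes in S284Y across temperature the median was -0.10 and the mean 0.10 with the test pointing up.

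**Figure D3:**
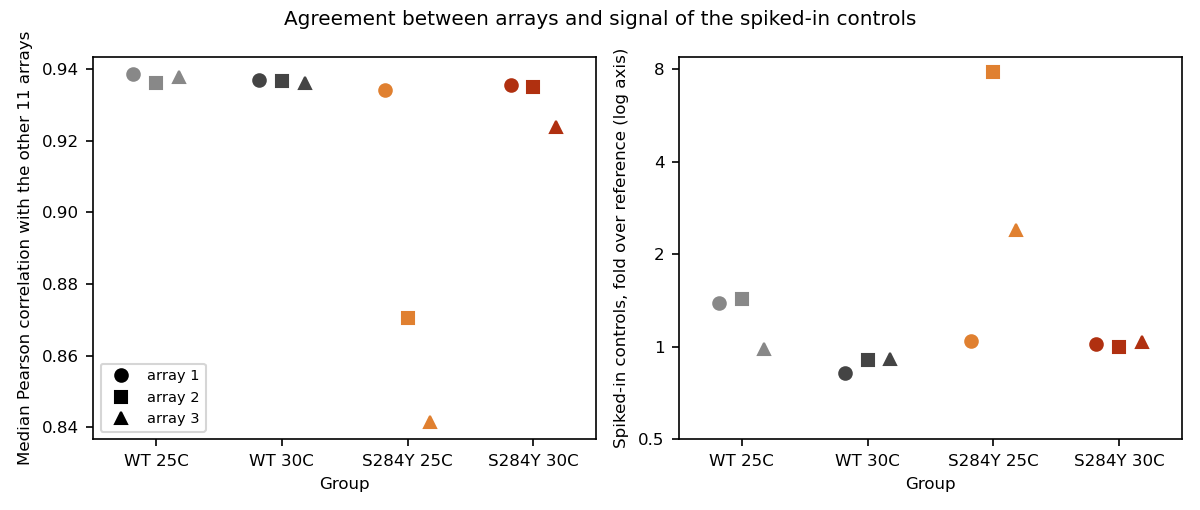
Left, median Pearson correlation of each array with the other 11; right, spiked-in controls as median fold over the other arrays (log axis). Arrays 2 and 3 of S284Y at 25C stand at 0.870 and 0.842 on the left and at 7.83 and 2.39 on the right.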

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

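The tests on spiked-in controls, on the genotype of the arrays that stand apart, on dilution and on scaling were chosen only after the results were seen, while the tests on probe sequence, on neighbours of U2af50 and on other splits of the arrays were written before.

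Control signals on arrays 2 and 3 of S284Y at 25C lie outside the main measurement and differ from the other 10 arrays. Spiked-in controls were 7.83 and 2.39 times their level on the other arrays (others 0.819 to 1.43), and the middle probe set of 18S ribosomal RNA read 2425 and 1722 (others 11.4 to 384). The 5' probe set of 18S read 1660.9 in array 2, but 40.7 in array 3, within the others (8.8 to 205.7). The 3' to 5' signal ratio, a sign of RNA quality, was 5.06 and 3.38 for Gapdh (others 2.29 to 3.30) and 3.93 and 5.32 for eIF4A (others 3.13 to 4.37), while that of actin, 2.25 and 2.81, lay within the others (2.04 to 3.18). These arrays correlated with the rest at 0.808 to 0.887, against 0.910 to 0.959 among the other 10, and the median residual SD of their group was 0.575 against 0.224 to 0.257 in the others. Little labelled sample RNA relative to the spikes stays open, since its test, the lower of the spike values at 2.39 against a highest of 1.43 elsewhere, is the observation that prompted it. Degraded RNA was not tested and stays open too. Flies without the S284Y genotype would show no shift of the genes called between genotypes at 30C. Over 343 such genes of 2-fold or more the lower shift was 0.564 ± 0.118 (bootstrap SE; highest WT 25C array 0.0234), which argues against it. The first version of that test, over all 934 genes, had left array 3 open at 0.0413 ± 0.0447, so the deciding test was chosen after. An effect of S284Y at 25C itself stays open: array 1 of the same group has a median correlation of 0.934, within 0.924 to 0.939 of the other groups, but 1 array decides nothing. The spiked-in controls of array 1 stood at 1.04. Arrays 2 and 3 correlated with each other at 0.821, the lowest value within the group (highest 0.887).

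The 59 probe sets that differed between genotypes at both temperatures (52 genes) could reflect sequence differences under the probes or a chromosome segment carried along with U2af50. For probe sequence, 4 of 7 other probe sets of the same genes, from CG30440, CG42748 and rhea, went in the direction of the call (exact binomial p = 1.0, median signed shift 0.534), which leaves it open. For a segment, 1 called gene lay within 200 tested genes on either side of U2af50 where 1.89 were expected (hypergeometric exact p = 0.855). This argues against a segment within that window as the source of most of these differences. With so few genes expected a small excess could be missed, and a larger segment was not tested and stays open. An effect of the mutation, or of other differences between the stocks, was not tested and stays open.

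Lower fat body and detoxification genes in S284Y at 30C might come from a larger share of germline tissue diluting the rest of the body, or from scaling. Dilution predicts that muscle, nervous system and photoreceptor genes fall alike. Their median (78 genes) was -0.04 against -0.60 for 31 fat body genes, a difference of 0.563 ± 0.181 (bootstrap SE over genes). An even dilution of all these tissues would not give such a gap. However, fat body was picked for its low values and both medians came from a fit already seen. The SE also leaves out the spread between arrays, so dilution is not excluded for fat body genes. For these genes, scaling is argued against by their median relative to all genes under quantile normalization, -0.663 ± 0.184 (bootstrap SE over genes). Neither test was run on detoxification genes, for which both stay open. An effect of S284Y at 30C on these tissues was not tested separately and stays open.

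By the interaction test with the preset correlation 11 lists moved, of which 0 did so with an estimated correlation and 5 lost the call without arrays 2 and 3 of S284Y at 25C. Their values were median differences of 0.63 for cell cycle, 0.35 for ovary, 0.34 for SR and hnRNP, -0.55 for digestive, -0.54 for immune, -0.46 for oxidative phosphorylation, -0.37 for testis, -0.37 for eggshell, -0.37 for fat body, -0.25 for mitochondrial ribosomal and -0.21 for detoxification genes. Of 100 ways to split the arrays, the real one among them, 7 moved as many lists (real 11, highest other 13), so a grouping by chance is not ruled out for the number of lists. For single probe sets the real count was 0, which every split must reach (100 of 100), so this comparison decides nothing. Separately, 96 splits called 0 and the highest 79 and 58. The splits changed genotype labels independently within each temperature. A full swap at 1 temperature turns a genotype difference shared by both temperatures into an interaction, and a partial swap adds it to the spread. The splits therefore do not stand for arrays without an interaction, and neither these counts nor the 7 splits decide the question.

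With 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. For changed probe sets 1 of 10, the real one, reached the real count in each comparison: 110 for genotype at 25C (highest other 0), 213 at 30C (0), 559 for temperature in S284Y (1) and 13 in WT (0). For moved lists it was 4 of 10 for genotype at 25C (real 7, highest other 12), 1 of 10 at 30C (11 and 8), 1 of 10 for temperature in S284Y (18 and 15) and 1 of 10 in WT (9 and 5).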

How the results depend on the processing

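No test in this part was chosen after the results were seen, except the fits without arrays 2 and 3 of S284Y at 25C, with array weights and without lysozymes. No named gene that passed reversed under any alternative. Values that had not passed crossed 0 for U2af38, U2af50, LysE, bam, Irbp, Psi and Hrb87F in at least 1 alternative. The interaction stayed at 0 probe sets in every fit except the one without array 1 of S284Y at 25C. Of 285 values of named genes, the number on the same side of the threshold was 285 with offset 64, 282 with offset 1, 275 with median centring, 273 with quantile normalization, 250 with WT 30C array 1 moved, 243 without the trend, 211 without arrays 2 and 3 and 197 with array weights. With only the 6 arrays compared, 133 of 237 such values stayed on the same side (74 weaker, 30 stronger). Counting a list once for each contrast in which it moved gives 56 results. Of these, 55 kept their call with the mean of a gene's probe sets, 53 with median centring and 44 with quantile normalization (2 reversed). It was 46 without S284Y 25C array 2, 46 without array 3, and 4 with the estimated correlation.

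Under quantile normalization 4 lists moved for genotype at 25C (7 as reported), ribosomal proteins turned to -0.0335 for genotype at 30C and to 0.13 for temperature in WT, the intronless difference in S284Y was -0.0920, and the correlation of temperature effects was 0.295. That correlation was 0.307 with offset 1, 0.360 with offset 64, and 0.432 without the dimmest 40%, where temperature in WT called 7. Without the trend, temperature called 128 in S284Y and 8 in WT. The cause of these changes was not tested.

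Only the 6 arrays compared gave 17 and 1106 changed probe sets for genotype at 25C and 30C, and 0 and 178 for temperature in S284Y and WT. By construction this fit leaves arrays 2 and 3 of S284Y at 25C out of the spread of the comparisons they are not in. No such fit can be made for the interaction, which needs all 4 groups. With WT 30C array 1 moved to 25C, genotype at 30C called 106, temperature 222 in S284Y and 0 in WT, 5 lists moved in WT, and the correlation of temperature effects was 0.248. The cause was not tested.

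Leaving out arrays 2 and 3 of S284Y at 25C leaves 1 array in that group, which is assumed to vary like the other groups. In that fit genotype at 30C called 1278 and temperature 183 in S284Y and 200 in WT. Lists moved were 2 for genotype at 25C and 7 for the interaction. Medians turned to -0.12 for digestive, 0.12 for ovary and -0.0191 for ribosomal protein genes (genotype at 25C) and to -0.00499 for SR and hnRNP genes (interaction). The intronless difference was 0.10 for genotype at 25C and -0.16 for temperature in S284Y, and the correlations were 0.337 (genotype) and 0.265 (temperature). With array weights, genotype at 30C called 1226, temperature 75 in S284Y and 277 in WT, 4 lists moved for genotype at 25C, and the genotype correlation was 0.357. These fits give the arrays that stand apart no or little weight; no other cause was tested.

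With the estimated correlation the lists moved were 0 and 2 for genotype at 25C and 30C, 1 and 1 for temperature in S284Y and WT, and 0 for the interaction. The intronless differences of 0.21, 0.19, -0.38 and -0.35 did not pass. Genes that vary together are not the whole reason. Immune and detoxification genes lost their interaction calls at estimated correlations of 3.36e-05 and -0.0039, below the preset 0.01. A call lost with the estimated correlation is therefore not by itself evidence that the genes of a list vary together. The cause was not tested. Matched on mean value, the intronless difference was 0.12 for genotype at 25C and -0.24 for temperature in S284Y. Without lysozymes it was 0.0688 and 0.15 for genotype and -0.25 and -0.26 for temperature, with fewer genes.

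With each array left out in turn, changed probe sets ranged from 48 to 885 and from 82 to 821 for genotype at 25C and 30C, from 17 to 2398 and from 1 to 99 for temperature in S284Y and WT, and from 0 to 84 for the interaction. Lists moved ranged from 4 to 11, 7 to 13, 15 to 19, 7 to 11 and 8 to 16 in that order. The intronless difference ranged from 0.10 to 0.38, 0.16 to 0.24, -0.48 to -0.28, -0.37 to -0.23 and -0.21 to 0.14, and the correlations from 0.183 to 0.359 (genotype) and 0.267 to 0.342 (temperature). The cause was not tested.

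The labels do not say what a replicate number marks. Deviations of same-numbered arrays correlated at -0.13 to 0.06 over 18 pairs, 0 of them above 0.1, and those of other pairs at -0.04 to 0.09, and not every array correlated best with its own number, so the numbers were not taken as pairs. With the replicate block, changed probe sets were 78, 151, 164, 1 and 0 in the order above. Signal over background limits what can be called: without detection calls, dim probe sets cannot be told from background, and the offset of 16 shrinks their differences. Of simulated 4-fold changes 54.5% (25C) and 62.1% (30C) were called between genotypes, and of 2-fold changes 20.9% and 25.4%, so absence from the calls is weak evidence of no change.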

Other observations

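No tests of new hypotheses are given here. The gene families below were picked by the stem of their names after the values were seen, and are described as values only.

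The maltase family (10 genes measured) had a median of -1.80 for S284Y against WT at 30C, with 5 lower and 0 higher, and 7 lower in the fit of the 6 arrays compared. The GstE family (14 genes) had a median of -0.68 there, with 5 lower and 1 higher, and cytochrome P450 genes (83) one of -0.28, with 9 lower and 1 higher. In the same comparison 1 of 18 neprilysin-like genes was lower (4 in the fit of the 6 arrays; median -0.47). For 30C against 25C in S284Y, 4 of 14 Jon proteases were lower (median -1.05), 3 of 15 ubiquitin-specific proteases higher (median 0.76) and 1 of 9 kinesin-like genes higher (median 0.90), and the fit of the 6 arrays called 0 in each.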
